A study of Panicum sumatrense with 28 samples.

How the data were processed

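RNA was sequenced from 10 tissues of little millet (Panicum sumatrense, a small-grained cereal), genotype JK-8, as 28 libraries. There were 3 libraries for each of 8 tissues and 2 for young root and vegetative stem. The growth and extraction protocols in the labels describe plants kept in a growth chamber, RNA taken with either of 2 extraction methods (which library had which is not given in the sources used here) and TruSeq libraries. Nothing in the labels says that replicates came from separate plants, so the p-values below measure the spread between these samples, which may be technical.

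The deposited table holds a non-negative expression signal for 101935 assembled transcripts in each library. Per the series design text, the authors assembled the reads de novo with Trinity and estimated abundances with kallisto as TPM, a read share corrected for transcript length. CASAVA, Trimmomatic and kallisto are named in the submitters' processing notes, and their versions are not given in the sources used here. The name of the deposited table says that the authors' values were scaled by TMM (trimmed mean of M-values), a factor per library that makes most transcripts comparable between libraries. The values carry this scaling: the sums of the libraries, divided by their geometric mean, ran from 0.661 in panicle early to 3.20 in young root, where unscaled TPM have the same sum in every library. Values of this kind keep no read totals, so the depth of the libraries is unknown, no counting interval was given, and no count model was used. A library in which a few transcripts take much of the RNA has fewer reads for all others, and the scaling factor then raises their values together with the sum.

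Each row is 1 isoform of the assembly, and no assembled gene had more than 1 row, so the planned tests of isoform usage and the sums per assembled gene could not be run. The table does not pair its identifiers with gene names, and no annotation of this species was used here. The planned gene lists (mineral uptake and transport, photosynthesis, storage, starch, cell cycle, cell wall, floral and pollen genes) and tissue markers were therefore not analysed here, and transcripts are named by their assembly identifier. A transcript of a de novo assembly can be a splice form, an allele or a copy from another subgenome, and near-identical copies share reads.

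The following was computed from the table. Every one of its value columns matched 1 sample by the code in the sample's title. Transcripts with a value of at least 1 in at least 2 libraries were kept, which left 77548. Tests were run with limma 3.58.1 in R 4.3.3 on log2(value + 1), with 1 mean per tissue over all 28 libraries, no covariates and an intensity trend in the moderated variance, which left 18 residual degrees of freedom. Differences are on the log2(value + 1) scale, which understates changes of low transcripts. A transcript was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1, two-sided. Differences among the 10 tissues were tested with limma's moderated F. A transcript was called elevated in a tissue when the largest of its 9 one-sided p-values against the other tissues passed 0.05 after adjustment and its log2 mean lay at least 1 above the next tissue. Sets elevated in several tissues were called in the same way against all tissues outside the set. Correlations between libraries, abundance shares and permutation tests were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

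The transcripts named were fixed by rule before the data were examined. Per comparison these were the largest rise and the largest fall among called transcripts whose libraries did not overlap between the groups, and per tissue the elevated transcript with the highest mean. Other transcripts are said to have been chosen after their values were seen. The comparisons, the tests and most alternatives were also fixed before the data were examined. The alternatives were other pseudocounts, filters and scalings, the replicate number as a block, the library identifier series as a covariate, library weights, fits of the compared groups only and leaving out each library. Quantile normalization and median centring, the latter chosen after the data were seen, act on the balance of higher and lower transcripts by construction, so shares given under them do not test that balance. The sample descriptions carry library identifiers of 2 series, here called A (15 libraries) and B (13 libraries). Series B holds vegetative stem, the panicle stages, radicle library 3 and young root library 2, so most tissues lie in 1 series only, and the covariate rests on radicle and young root.

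Replicate numbers did not pair libraries: the deviations of same-numbered libraries of different tissues from their tissue means correlated at 0.0021 on average, and 3 of 118 pairs passed 0.1. The closest replicate pair correlated at a Spearman's rho of 0.874, so no library looked like a copy of another.

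The limma steps were tested on simulated data with the means and spread of the 77548 transcripts and known changes. Of 100 transcripts changed by 3 on the log2 scale, 84 were recovered for young root against young leaf, 82 for radicle against plumule, 63 for the difference of these contrasts, 94 for seedling parts against germinating seed and 78 for vegetative stem against crown meristem. Recovery was 90, 87 and 86 for panicle mid against early, late against mid and late against early. At a change of 1.5 it ranged from 8 of 100 for the difference of the contrasts to 45 of 100 for panicle late against mid. Between 2 and 11 unchanged transcripts were called per comparison. For the elevated transcripts, 70.0% (vegetative stem) to 82.0% (panicle mid) of 200 were recovered with 0 false calls by limma's adjusted test. The simulated values were normal, with 1 spread per transcript in all tissues and no floor at 0, so recovery may differ in the real values. Unchanged transcripts had the same level in every tissue. The 0 false calls therefore do not cover transcripts that are equally high in several tissues.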

Results

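The data cover the life of the little millet plant in 10 tissues: germinating seed at 2 days after sowing, radicle and plumule (the embryonic root and shoot) at 3 days, young leaf and young root at 13 days, crown meristem at 26 days, vegetative stem at 48 days, and the panicle (the branched flower head that bears the grain) at 61, 73 and 85 days, called early, mid and late. The series title names mineral uptake, a task of the root, as the purpose of the atlas. Values are TMM-scaled TPM for assembled transcripts, each given as mean ± SD over the libraries of a tissue (n = 3, or n = 2 for young root and vegetative stem). Read depth cannot be read from such values.

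Of the 77548 transcripts kept, 10023 had a value of 1 or more in all 28 libraries, and 13957 had a mean of 1 or more in all 10 tissues. Plumule had the most transcripts at 1 or more, 41696 ± 4383, and radicle the fewest, 27110 ± 756, followed by young root with 27940 ± 539. Plumule also had 10763 transcripts with a mean of 1 or more in no other tissue, but 5513 transcripts reached 1 only in its library 1.

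The tissues differed in how much of the library total a few transcripts took. In young root the 10 most abundant transcripts held 64.7% ± 7.0 of the total, in radicle 34.7% ± 7.07, in panicle late 32.2% ± 4.77 and in young leaf 10.1% ± 0.155. Vegetative stem was lowest with 3.66% ± 0.521. In young root between 2 and 4 transcripts made up 50% of the total, whereas panicle early needed 1945 ± 292. Panicle late shared none of its top 10 transcripts with germinating seed, radicle, plumule, young leaf, young root, crown meristem, vegetative stem or panicle early, and 1 with panicle mid.

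**Figure D1:**
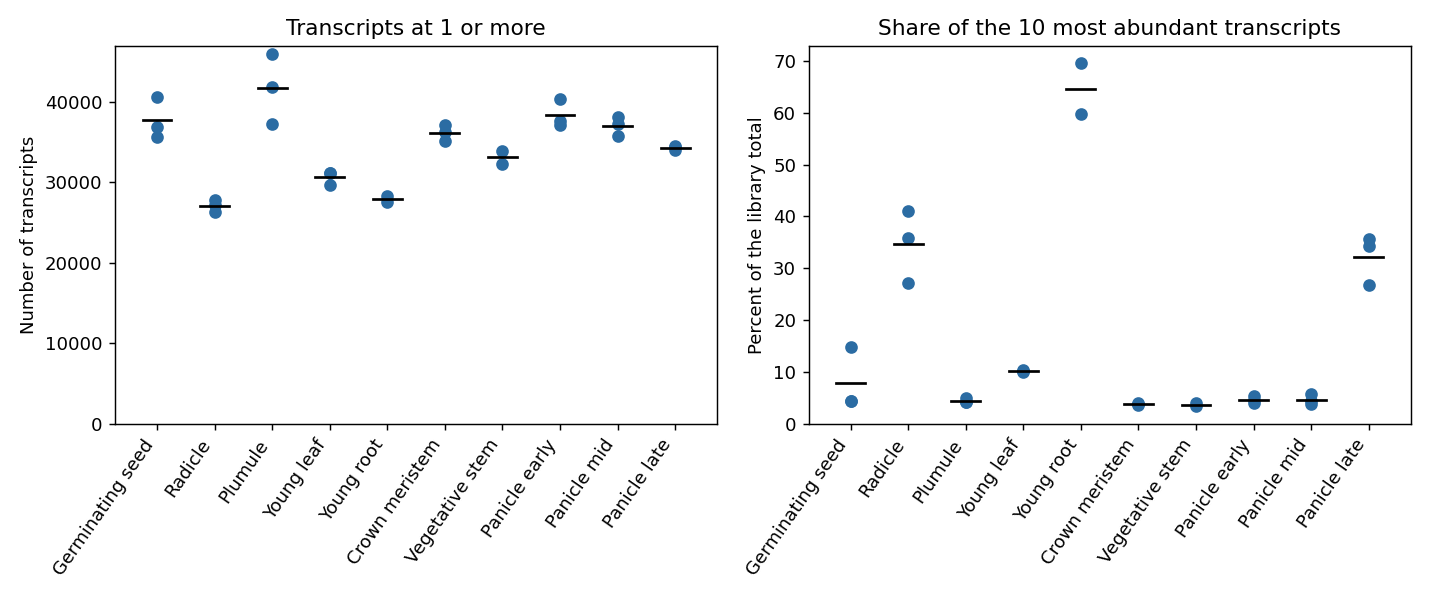
Number of transcripts at a value of 1 or more (left) and percent of the library total held by the 10 most abundant transcripts (right), by tissue. Points are libraries and bars are tissue means; the 2 young root libraries lie at 59.7% and 69.6% on the right, above the other 26.

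The transcript TRINITY_DN7657_c1_g1_i63, chosen after its values were seen, was the most abundant in both root tissues. It also ranked first in the 3 germinating seed libraries and in crown meristem libraries 2 and 3, at 0.721% to 6.77% of their totals. It made up 32.8% and 42.7% of the young root totals and 17.0% to 29.5% of the radicle totals, against 0.174% to 0.252% in plumule. Its value was 1135540 ± 328905 in young root and 2049 ± 98.2 in young leaf, a log2 difference of 9.08 (SE 0.61, limma adjusted p = 6.0e-11). Radicle exceeded plumule by 7.66 (SE 0.55, adjusted p = 1.0e-10). Germinating seed library 1 stood apart, with 73379 against 7082 and 7909 in the other libraries of that tissue. A further abundant root transcript, TRINITY_DN22072_c0_g2_i1, also chosen after its values were seen, had 356033 ± 39850 in young root and 478 ± 36.3 in young leaf, a log2 difference of 9.54 (SE 0.57, adjusted p = 8.0e-12).

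By Spearman's rho over transcripts, which are not independent replicates, 27 of the 28 libraries had their closest library in their own tissue. The exception was plumule library 1, whose closest library was panicle early library 1 (0.782), and it was no exception by Pearson's r of the log2 values, with a filter at 5 or with a filter at a mean of 20, where all 28 libraries were closest to their own tissue. Mean rho within a tissue ran from 0.697 in young root to 0.874 in vegetative stem. The highest mean rho between tissues were those of vegetative stem with crown meristem (0.815) and panicle mid with late (0.815). Radicle and young root were each other's closest tissue at 0.646, the lowest rho of any tissue with its closest. In plumule the mean rho within the tissue, 0.743, lay below its mean with vegetative stem, 0.747: libraries 2 and 3 correlated at 0.833, and library 1 with them at 0.717 and 0.678. The farthest pair was radicle and young leaf, 0.505.

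**Figure D2:**
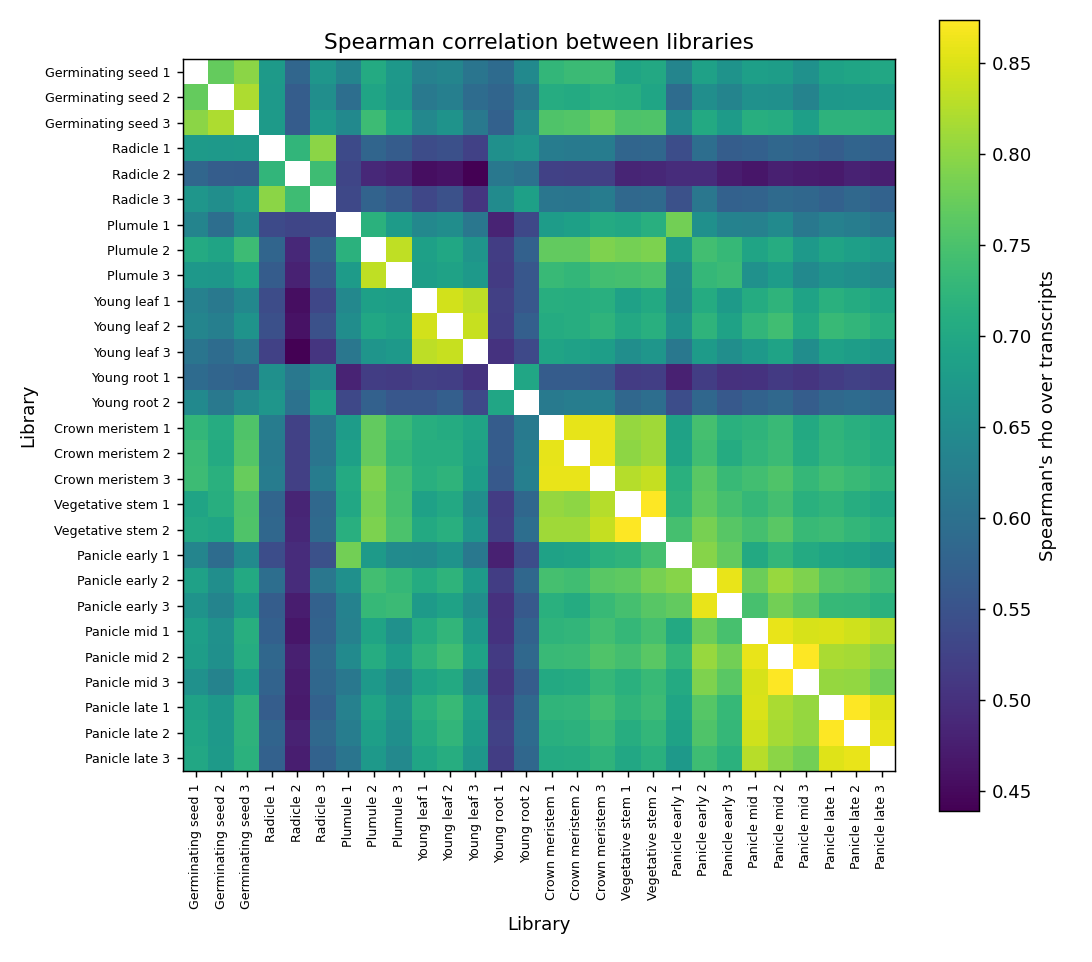
Spearman's rho between all pairs of the 28 libraries over 77548 transcripts, with libraries on both axes and rho as colour. Libraries of a tissue form blocks along the diagonal, and plumule library 1 and panicle early library 1 correlate at 0.782 across tissues.

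Over the 10 tissues, 46410 of 77548 transcripts (59.8%) differed by limma's moderated F (adjusted p below 0.05). Of the kept transcripts, 7771 were elevated in 1 tissue above each of the other 9. With the scaling as deposited, young leaf had the most, 2053, followed by radicle with 1637, panicle mid with 1017, young root with 1000, panicle late with 675, panicle early with 638, germinating seed with 304, plumule with 254, vegetative stem with 126 and crown meristem with 67. The order depended on the scaling: with median centring radicle had 3198, while young leaf reached at most 2291 over the alternatives. The sets differed in abundance: the panicle late set took 43.3% ± 4.81 of the totals of its own libraries, the young leaf set 41.7% ± 1.43, the young root set 20.0% ± 1.39 and the radicle set 18.1% ± 2.83, while the panicle early set took 2.18% ± 0.203 and the crown meristem set 0.232% ± 0.0299. The count depended on single libraries for 4 tissues. It was 840 for germinating seed without its library 1 and 1757 for plumule without its library 1. For crown meristem it was 108, 109 and 247 without its libraries 1, 2 and 3. It also rose for young root without its library 2 and fell for plumule without either vegetative stem library. Those fits left 1 library in a tissue, with its spread taken from the other tissues, so their counts carry less weight.

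**Figure D3:**
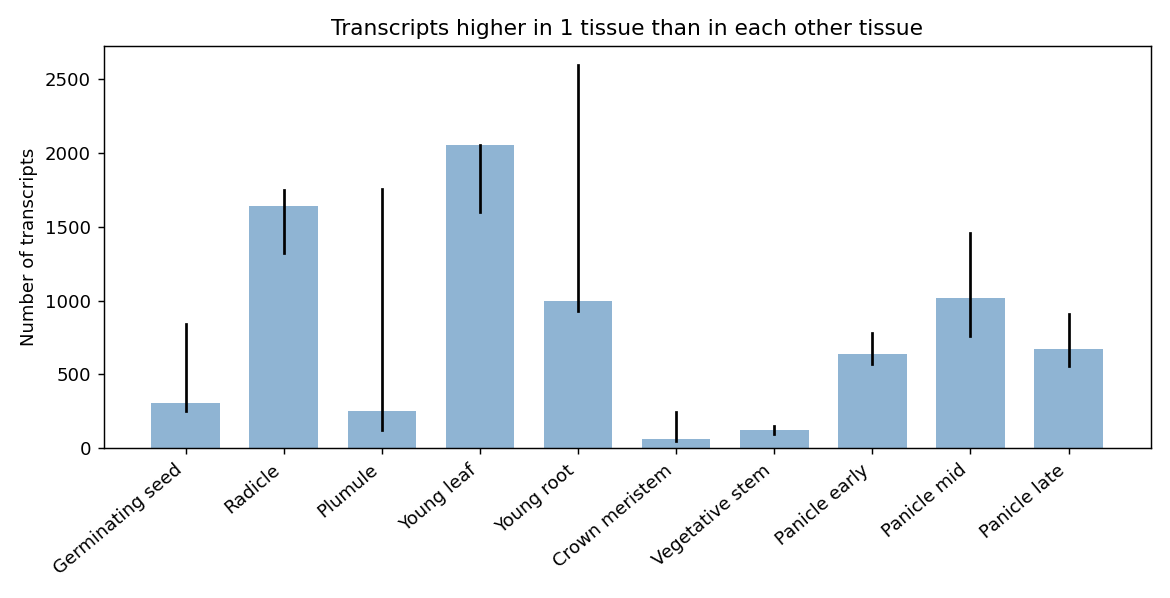
Number of transcripts elevated in each tissue above each of the other 9 tissues (bars), with lines from the lowest to the highest count when any 1 of the 28 libraries was left out. Young leaf has 2053 and crown meristem 67, and the line for plumule reaches 1757. The upper end for young root and the lower end for plumule come from fits that leave 1 library in a tissue.

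The next-highest tissue of the elevated transcripts was counted for each set. Of the radicle set, 716 of 1637 were counted with germinating seed next, and of the crown meristem set 33 of 67. Transcripts listed at 0 in every other tissue have no next tissue, but in these sets they were counted under germinating seed. They numbered 77 in the radicle set and 26 in the crown meristem set. The crown meristem count therefore does not show that germinating seed was its next tissue. Panicle late was next for 604 of 1017 panicle mid transcripts and for 72 of 304 germinating seed transcripts, and panicle mid for 373 of 675 panicle late and 284 of 638 panicle early transcripts. Young root had radicle next in 344 of 1000 cases, young leaf had plumule in 475 of 2053, plumule had vegetative stem in 103 of 254, and vegetative stem had crown meristem in 50 of 126. When tissues were joined, 854 transcripts were elevated in radicle and young root together above all other tissues, 361 in panicle mid and late, 124 in germinating seed and radicle, 107 in germinating seed and panicle late, 89 in plumule and young leaf, 62 in the 3 panicle stages, 15 in panicle early and mid, 8 in crown meristem and vegetative stem and 2 in plumule and panicle early.

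The most abundant elevated transcript of 6 tissues lay far above the next tissue; the log2 differences are between means of log2 values, so they differ from ratios of the means given. TRINITY_DN17263_c0_g1_i1 had 3686 ± 1450 in germinating seed and 6.29 ± 7.35 in panicle late, the next tissue (log2 difference 9.64, limma adjusted p = 2.5e-09). TRINITY_DN58295_c0_g1_i1 had 64952 ± 12991 in panicle late and 1014 ± 1581 in panicle mid (9.17, adjusted p = 0.0020), and its panicle mid values were 2835, 1.35 and 204 in libraries 1, 2 and 3. TRINITY_DN16659_c0_g2_i1 had 1374 ± 393 in panicle early and 76.2 ± 109 in panicle mid (5.45, adjusted p = 0.0021). TRINITY_DN5408_c0_g1_i2 had 968 ± 256 in crown meristem and 21.3 ± 6.88 in young root (5.44, adjusted p = 0.00015). TRINITY_DN13480_c0_g1_i5 had 1359 ± 1388 in panicle mid, a wide spread, and 20.5 ± 4.06 in panicle late (4.92, adjusted p = 0.0041). TRINITY_DN13091_c0_g1_i1 had 88283 ± 18632 in young root and 5646 ± 4215 in radicle (4.53, adjusted p = 0.00013). With a pseudocount of 0.1, TRINITY_DN58295_c0_g1_i1 (9.41), TRINITY_DN16659_c0_g2_i1 (5.55), TRINITY_DN5408_c0_g1_i2 (5.50) and TRINITY_DN13480_c0_g1_i5 (4.98) no longer passed the adjusted p, although their log2 differences were no smaller. Calls also ended with quantile normalization for TRINITY_DN58295_c0_g1_i1 (6.90) and TRINITY_DN13091_c0_g1_i1 (1.67), for TRINITY_DN16659_c0_g2_i1 (4.52) without germinating seed 1, radicle 2, plumule 1, panicle early 1 and panicle mid 1 together, an alternative chosen after the data were seen, and without panicle mid library 3 for TRINITY_DN13480_c0_g1_i5 (3.85).

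In the other 4 tissues the margin was smaller. TRINITY_DN10385_c0_g1_i3 had 676 ± 44.5 in plumule and 219 ± 6.16 in vegetative stem (log2 difference 1.62, limma adjusted p = 0.0051). TRINITY_DN4141_c0_g1_i10 had 431 ± 40.3 in vegetative stem and 149 ± 37.1 in plumule (1.55, adjusted p = 0.017). Near the threshold were TRINITY_DN36129_c0_g1_i1, with 23873 ± 1914 in young leaf and 11068 ± 2365 in plumule (1.13, adjusted p = 0.039), and TRINITY_DN91580_c0_g1_i1, with 11012 ± 4092 in radicle and 5253 ± 372 in germinating seed (1.01, adjusted p = 0.049). These last calls held in 19 and 12 of 41 alternatives; they were lost with a common sum (0.68 and 0.36), with quantile normalization (0 and -0.44) and without many single libraries, those of other tissues included. The calls of TRINITY_DN10385_c0_g1_i3 and TRINITY_DN4141_c0_g1_i10 ended with the library series as a covariate (both 1.40), without vegetative stem library 1 (1.65 and 1.46) and without library 2 (1.59 and 1.65), and that of TRINITY_DN4141_c0_g1_i10 also with a pseudocount of 0.1 (1.56), the filter at a mean of 20 (1.55) and without plumule library 2 (1.33).

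Young root and young leaf, both taken at 13 days, were compared because the atlas asks about uptake. Of 77548 transcripts, 9755 were higher in young root (median log2 difference 2.33) and 12469 lower (median -2.15); 1617 were higher and 1651 lower by at least 16-fold. The largest rise was TRINITY_DN4135_c0_g2_i1, with 33191 ± 7371 in young root and 1.38 ± 2.39 in young leaf (log2 difference 14.21, SE 1.0, limma adjusted p = 1.3e-10). It was also present in radicle at 1391 ± 1155. The largest fall was TRINITY_DN61880_c0_g1_i1, with 4990 ± 237 in young leaf and listed at 0 in both young root libraries (adjusted p = 2.0e-13). The share of calls that were lower depended on the scaling: 56.1% as deposited, 77.5% with libraries rescaled to a common sum, 55.2% with quantile normalization and 49.6% with libraries centred on their median.

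Radicle and plumule are the first root and shoot, both taken at 3 days. Here 7483 transcripts were higher in radicle (median log2 difference 2.13) and 17586 lower (median -2.02). The largest rise was TRINITY_DN4622_c0_g2_i1, with 4160 ± 1181 in radicle and 0.387 ± 0.491 in plumule (log2 difference 11.57, SE 0.27, limma adjusted p = 8.4e-18); young root had 76.1 ± 11.2. The largest fall was TRINITY_DN34287_c0_g2_i1, which fell by 9.50 (SE 0.64, adjusted p = 4.3e-11) from 5650 ± 2168 in plumule to 6.97 ± 3.98 in radicle, and had 6366 ± 246 in young leaf. The lower share was 70.2% as deposited, 82.0% with a common sum, 54.1% with quantile normalization and 54.6% with median centring. Over all transcripts the median log2 difference was -0.37 as deposited and -0.03 after quantile normalization.

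The root-shoot differences at 3 and 13 days overlapped. Transcripts higher in the root at both ages numbered 4101, against 941 expected of independent lists, and 7561 were lower in the root at both ages, against 2828. Opposite directions were rarer than independent lists give: 921 were higher in young root but lower in radicle (2212 expected), and 297 the reverse (1203 expected). Over transcripts the log2 differences correlated at a Pearson's r of 0.552 and a Spearman's rho of 0.420; no libraries are shared between these contrasts, and transcripts are not independent replicates.

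The difference between the contrasts was tested as an interaction. The root-shoot difference was higher at 13 days for 11178 transcripts and lower for 6204. Of these 17382, 3514 were called in the same direction at both ages, 5366 only at 13 days, 6216 only at 3 days, 1218 in opposite directions and 1068 at neither age. The abundant root transcript TRINITY_DN7657_c1_g1_i63 did not pass (log2 difference 1.42, SE 0.82, limma adjusted p = 0.25), while TRINITY_DN22072_c0_g2_i1 did (2.25, SE 0.76, adjusted p = 0.034). The lower share was 35.7% as deposited, 42.7% with a common sum, 53.5% with quantile normalization and 48.0% with median centring. Over all transcripts the median log2 difference was 0.26 as deposited and 0 after quantile normalization.

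Between germinating seed at 2 days and the mean of radicle and plumule at 3 days, 3307 transcripts were higher in that mean and 7735 lower. Of these, 966 were higher and 3198 lower in every radicle and plumule library than in every germinating seed library. The other calls on the mean can come from a single part. TRINITY_DN88119_c0_g1_i1 had the largest rise, from 1.47 ± 2.54 in germinating seed to 227 ± 148 in radicle and 174 ± 70.4 in plumule (log2 difference 6.62, SE 0.56, limma adjusted p = 2.1e-08). TRINITY_DN17263_c0_g1_i1 had the largest fall, from 3686 ± 1450 to 1.15 ± 0.992 in radicle and 0.660 ± 1.14 in plumule; it fell by 11.03 (SE 0.57, adjusted p = 1.1e-11). The lower share was 70.1% as deposited, 58.8% with quantile normalization and 41.9% with median centring.

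Panicle development was followed in 2 steps, with all libraries in series B. From early to mid, 4467 transcripts rose and 3863 fell. The falling share of 46.4% became 50.1% with a common sum and 52.2% with only these libraries in the fit. It was 50.7% without early library 1 and 50.6% without mid library 3, so neither direction prevailed. Median centring, which gave 50.8%, acts on this balance itself and is not counted here. The largest rise was TRINITY_DN34622_c0_g1_i1, listed at 0 in the 3 early libraries and at 782 ± 128 in panicle mid (limma adjusted p = 1.4e-09), and the largest fall TRINITY_DN7690_c0_g1_i4, which fell by 6.98 (SE 0.51, adjusted p = 1.6e-09) from 310 ± 120 to 2.56 ± 4.0. From mid to late, 2176 rose and 3999 fell. TRINITY_DN31619_c0_g1_i3 rose from 87.9 ± 145 to 21456 ± 4248 (log2 difference 10.56, SE 1.13, adjusted p = 1.3e-06), and TRINITY_DN32930_c0_g1_i2 fell by 6.50 (SE 0.69, adjusted p = 1.2e-06) from 181 ± 132 to 0.743 ± 0.664. The panicle mid values of TRINITY_DN31619_c0_g1_i3 were 255, 0.167 and 8.24 in libraries 1, 2 and 3, so its mid mean rests on library 1. The mid-to-late result rests on the shared estimate of spread: with only these libraries in the fit 452 transcripts were called, and the rise of TRINITY_DN31619_c0_g1_i3 had an adjusted p of 0.11 (1.3e-06 above; its alternatives ran from 2.8e-10 to 0.11). With a common sum 11834 were called, and the lower share was 87.5%, against 64.8% as deposited, 54.2% with quantile normalization and 54.6% with only these libraries.

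Transcripts that rose from early to mid and fell from mid to late numbered 1835, which was 41.1% of those that rose in the first step. Independent lists would share 230. Rises in both steps numbered 262 (125 expected), falls in both 302 (199 expected), and falls then rises 180 (108 expected). Both steps share the panicle mid libraries. When 1 of these was used in one step and the other 2 in the other step, an alternative chosen after the data were seen, rises then falls numbered 567 to 1268 over the 6 divisions, 4.0 to 9.97 times the number of independent lists, rises in both steps 39 to 771 (0.724 to 6.50 times), falls in both 66 to 696 (0.991 to 3.33 times) and falls then rises 89 to 98 (0.931 to 2.37 times). Only rises then falls exceeded independent lists in every division. The expected numbers are taken over all kept transcripts, including those too low in the panicle to be called in either step. With the panicle mid libraries shared, every pair of directions exceeded its expected number. A transcript that rose to panicle mid is present there and so has room to fall. The excess of rises then falls therefore cannot show that the steps are linked. Each division left 1 panicle mid library alone in a step and took its spread from the fit of all 28 libraries. The divisions therefore do not remove the dependence on the shared spread. With only the mid and late libraries in the fit, 452 transcripts were called from mid to late, fewer than the 1835.

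From early to late, 4995 transcripts were higher and 6698 lower. The largest rise was TRINITY_DN22841_c0_g1_i1, from 1.90 ± 1.05 in panicle early to 58472 ± 10342 in panicle late (log2 difference 14.36, SE 1.63, limma adjusted p = 8.1e-07). Its panicle mid values were 2901, 0.640 and 48.6 in libraries 1, 2 and 3. The largest fall was TRINITY_DN16659_c0_g2_i1, which fell by 9.54 (SE 1.02, adjusted p = 3.4e-07) from 1374 ± 393 to 1.59 ± 2.75. The lower share was 57.3% as deposited and 80.6% with a common sum, which moved the median log2 difference of all transcripts from 0 to -0.36 (to -0.13 from mid to late).

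Between vegetative stem at 48 days and crown meristem at 26 days, 815 transcripts were higher in the stem and 1902 lower. TRINITY_DN7658_c0_g3_i1 had 89.9 ± 17.8 in the stem and was listed at 0 in the 3 crown meristem libraries (limma adjusted p = 4.1e-06). TRINITY_DN5408_c0_g1_i2 had 968 ± 256 in crown meristem and was listed at 0 in both stem libraries (adjusted p = 1.2e-08). All stem libraries lie in series B and all crown meristem libraries in series A, so series and tissue are confounded here; with the series as a covariate, which rests on radicle and young root, 1769 were called. Without stem library 1 or 2 the counts were 1518 and 1660, and the lower share of 70.0% became 46.7% without stem library 2 and 58.0% with quantile normalization.

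**Figure D4:**
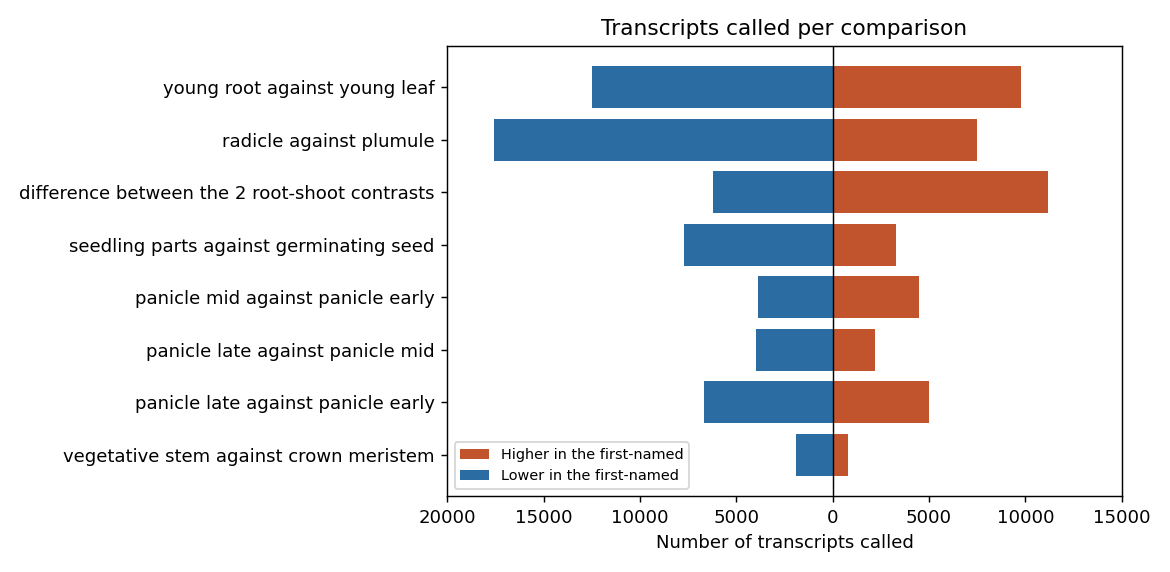
Number of transcripts called higher (right) and lower (left) in the first-named tissue for each comparison, by limma over 77548 transcripts with the scaling as deposited. Radicle against plumule has 7483 higher and 17586 lower; quantile normalization and median centring act on this balance by construction, and the larger side turned under median centring for young root against young leaf (49.6% lower), seedling parts against germinating seed (41.9%) and panicle mid against early (50.8%), under quantile normalization for the difference of the contrasts (53.5%), and without stem library 2 for vegetative stem against crown meristem (46.7%).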

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

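The test of the excess that mixing would need, also used for libraries sharing an index, both tests on panicle mid library 1 and the weighting of both tissues alike for read depth were chosen only after the result was seen. For the needed excess 2 readings were looked at before 1 was taken, and both are given. The further definitions of the mixing, late-transcript and read-depth tests were added after a first result was seen, because the outcome turned on the definition.

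The root-shoot difference was not the same at 3 and 13 days: the interaction test called 17382 transcripts (11178 higher and 6204 lower at 13 days). Radicle was compared with plumule and young root with young leaf, so the ages also differ in the parts compared.

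Plumule library 1 was closer to panicle early library 1 (rho 0.782) than to its own tissue, which none of the 3 alternatives run repeated. In these libraries and in none of the other 26, 3533 transcripts reached 1. The next cross-tissue pair, with 898, was radicle library 2 with plumule library 1 again, so it is no independent background. The highest cross-tissue pair without plumule library 1 shared 613 (plumule library 3 and panicle early library 3). An added source of RNA common to plumule library 1 and panicle early library 1 may account for the 3533. Neither its organism nor a biological explanation was tested. Panicle early reads mixed into plumule library 1 are argued against: over 519 transcripts of panicle early the median log2 excess in plumule library 1 was 0 (quartiles -0.10 and 0.10), and it was 0 in all 9 definitions tried. Plumule reads in panicle early library 1 are argued against as the whole cause: over 260 plumule transcripts the median excess was 0.0305 (quartiles -0.10 and 0.68; medians 0 to 0.19 over 9 definitions), while the transcripts below 1 in the other 26 libraries would need 0.123 to 0.231 times the values of plumule library 1, which gives a median excess of at least 0.58. In each of 45 combinations of definition and share the upper quartile observed lay below the median needed, although the lower quartile of the shortfall, taken transcript by transcript, was above 0 in 40 and 0 in the other 5, so a smaller share stays possible. The labels give both libraries the same index sequence in different series. Carry-over between them, being reads of one in the other, is argued against as the whole cause by the same values in both directions. Even so, among pairs of different tissues between the series, 4 of the 5 highest share an index (3533, 613, 507 and 193 exclusive transcripts). The 181 such pairs with different indexes had at most 157, and this was left unexplained.

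Panicle mid library 1 held the 10 most abundant transcripts of panicle late at 3.83% of its total, against 0.000734% and 0.157% in libraries 2 and 3. Carry-over from radicle library 1, which has the same index, is argued against, since the median of 116 late transcripts there was 0. Late panicle material or reads at 1 common share may be the source but cannot be told from unequal changes of these transcripts: their ratios to panicle late spread 1.47 times as widely as those of a single late library, and over 9 definitions this ran from 1.26 to 1.58, on both sides of the bound of 1.5. A panicle that ripened earlier, which the stages of the design allow, is such material and was not tested apart.

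More transcripts were lower than higher in young root against young leaf (56.1%). A low read depth of the young root libraries stays open: among the 5320 called transcripts with a mean of both tissue means of 20 or more the lower share was 57.9%, but over 48 settings of filter, minimum and library left out it ran from 32.6% to 61.4%, at 55% or more in 23 and at 50% or less in 16. The share fell as the minimum rose. With no library left out it was 58.1%, 57.9%, 53.5% and 50.1% at minima of 10, 20, 50 and 100 for the mean of both tissue means. For the mean of the other 23 libraries it was 60.6%, 56.8%, 44.6% and 34.3%. More lower than higher calls were thus a trait of the less abundant transcripts. The planned filter, a mean over 3 leaf and 2 root libraries, favoured transcripts high in leaf, so its share of 63.5% is not used. The scaling between libraries stays open too: the share with quantile normalization, 55.2%, met the bound of 55% set beforehand, but that scaling acts on the balance itself, so it decides nothing. A biological difference between root and leaf was not tested apart from these.

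Other splits of the same libraries were counted for the comparisons with at least 3 libraries per group. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split gave the most calls in each case: 25069 for radicle against plumule (highest other 1904), 8330 for panicle mid against early (209), 6175 for late against mid (567) and 11693 for late against early (15), each with 1 split as large, the real one. For the F test over the 10 tissues, 1 of 100 splits, the real one, gave 46410 or more, and the highest other gave 3481. Random divisions of the libraries thus did not reach the real count. They treat the libraries as independent, so they cannot tell tissue differences from repeats of the same sample. For seedling parts against germinating seed the count cannot decide, and chance was not excluded by it: 5 of 100 splits gave 11042 or more, the real one included, and the highest other gave 21533. The 4 larger splits kept the 3 radicle or the 3 plumule libraries together (21533, 18249, 14980 and 13049 calls) and so carry the difference between these tissues, a structure of the samples.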

How the results depend on the processing

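Median centring of the libraries, dividing the panicle mid libraries between the steps, the levels of both tissues weighed alike for young root against young leaf, the filter at a mean of 20, sums per assembly component, and leaving out plumule library 1 with panicle early library 1 or the 5 libraries that stand apart (these and germinating seed 1, radicle 2 and panicle mid 1) were chosen after the data were seen. Read depth is unknown, and low transcripts sit near the floor. The planned isoform-usage tests and sums per assembled gene were not run, since each assembled gene has 1 isoform. Where a library was left out of a tissue with 2, or panicle mid was divided between the steps, the lone library was assumed to vary like the other groups. Counts within 1.5 times the value in the report are not listed. Of 692 values under alternatives of the 24 named values of 21 transcripts, 623 kept their direction and side of the threshold, 68 lost the threshold (TRINITY_DN36129_c0_g1_i1 in young leaf fell to 0 with quantile normalization) and 1 reversed, TRINITY_DN91580_c0_g1_i1 in radicle with quantile normalization (-0.44). The cause was not tested unless stated.

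With a pseudocount of 0.1, the elevated transcripts numbered 169 in germinating seed, 900 in radicle, 85 in plumule, 1354 in young leaf, 435 in young root, 35 in crown meristem, 40 in vegetative stem, 454 in panicle mid and 358 in panicle late. With a pseudocount of 5, which shrinks differences of low values, the comparisons gave 13912 (young root against young leaf), 14004 (radicle against plumule), 4463 (seedling parts against germinating seed), 3831 (panicle mid against early), 2954 (late against mid), 5601 (late against early) and 1220 (vegetative stem against crown meristem), and the elevated were 30 in crown meristem, 54 in vegetative stem, 294 in panicle early and 626 in panicle mid. A filter at 5 left 25 elevated in crown meristem, 41 in vegetative stem and 307 in panicle early, from fewer transcripts. The filter at a mean of 20 tested 7736 transcripts, so all counts were lower: 5057, 5270, 2994, 1475, 1250, 2386 and 686 for the comparisons in the order above, 4226 for the difference of the root-shoot contrasts, 7665 for the F test, and for the elevated 59 in germinating seed, 493 in radicle, 91 in plumule, 658 in young leaf, 103 in young root, 1 in crown meristem, 2 in vegetative stem, 17 in panicle early, 46 in panicle mid and 113 in panicle late.

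With each library rescaled to a common sum, panicle late against mid gave 11834 and vegetative stem against crown meristem 4251, and the elevated were 1067 in radicle, 1284 in young leaf, 348 in young root, 124 in crown meristem, 226 in vegetative stem, 1001 in panicle early and 432 in panicle late. Quantile normalization gave 154 elevated in plumule and 199 in vegetative stem, and median centring 172 in germinating seed, 3198 in radicle and 132 in plumule. With the library series as a covariate, vegetative stem against crown meristem gave 1769, and the elevated were 171 in germinating seed, 88 in plumule, 1214 in young leaf, 31 in crown meristem and 54 in vegetative stem. Library weights gave 5866 for vegetative stem against crown meristem and 1216 elevated in plumule and 594 in young root. With only the compared groups in the fit, the spread rests on fewer libraries: 13581 for young root against young leaf, 3312 for panicle mid against early, 452 for late against mid and 1135 for vegetative stem against crown meristem. The replicate number as a block moved no count by 1.5 times (21929 for young root against young leaf, 25050 for radicle against plumule).

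Without plumule library 1 and panicle early library 1, 1555 were elevated in plumule; without the 5 libraries, 744 in germinating seed and 1450 in plumule. Leaving out each library in turn gave 20574 to 23545 calls for young root against young leaf, 24143 to 25743 for radicle against plumule, 15438 to 18205 for the difference of the contrasts, 10238 to 12021 for seedling parts against germinating seed, 7033 to 7761 for panicle mid against early, 4554 to 7233 for late against mid, 10086 to 10952 for late against early and 1518 to 2486 for vegetative stem against crown meristem. The elevated ran from 255 to 840 in germinating seed (840 without its library 1), 124 to 1757 in plumule (1757 without its library 1, 146 and 124 without stem libraries 1 and 2), 931 to 2593 in young root (2593 without its library 2) and 49 to 247 in crown meristem (108, 109 and 247 without its libraries 1, 2 and 3). All 28 libraries had their closest library in their own tissue under each of 3 alternatives, against 27 in the report.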

Other observations

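The tests of a common source for 2 root transcripts and of the same-index pairs were chosen only after the result was seen.

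The levels of TRINITY_DN7657_c1_g1_i63 and TRINITY_DN22072_c0_g2_i1, the abundant root transcripts chosen after their values were seen, were compared over the 8 tissues other than young root and radicle, for which they had been chosen. There their tissue means correlated at a Spearman's rho of 0.738 (exact permutation p = 0.046) and their log2 means at a Pearson's r of 0.964 (exact permutation p = 0.0010). Over all 10 tissues the values were 0.867 and 0.995, which restate the choice and carry no weight. The ratio of their means ran from 2.08 to 4.64. Among the 8 tissues both means were highest in germinating seed, where library 1 stood apart. It had 73379 against 7082 and 7909 in the other libraries, and 17975 against 1782 and 2900 for TRINITY_DN22072_c0_g2_i1. No other abundant root transcripts were compared in this way. The correlation therefore cannot tell 1 common source, such as parts of 1 transcript or a shared origin of the RNA, from separate transcripts with a similar tissue pattern.

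Transcripts elevated in panicle late may mark the grain and be carried over into germination, a hypothesis tested on the 675 of them. Their median value was 0.347 in germinating seed and 0 in each of radicle, plumule and young leaf, and 34.1% had a mean of 1 or more in germinating seed against 13.9%, 14.4% and 15.9%. The medians were 0.169, 0.182 and 0.0980 in germinating seed libraries 1, 2 and 3. These values lie near the floor, where low expression and stray reads also give such levels, and no test set them apart. The 10 most abundant transcripts of panicle late held 32.2% of its totals and 0.0088% ± 0.0074 of the germinating seed totals. Their share was 0.0070% ± 0.0056 in young root, 0.0042% in radicle, 0.0040% in young leaf and 0.0015% in plumule.

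The 10 same-index pairs of different tissues other than plumule library 1 with panicle early library 1 shared a median of 21 exclusive transcripts. The median was 10 over the 181 other pairs of different tissues between the series. Their mean excess of log2(exclusive + 1) over other pairs of the same tissues was 0.35 (exact one-sided permutation p = 0.021, 8 of 10 pairs above 0). They ranged from 613 (plumule library 3 and panicle early library 3), 507 (germinating seed library 2 and vegetative stem library 1) and 193 (young leaf library 1 and panicle mid library 3) to 3 (young leaf library 3 and panicle late library 2), and 4 of them, with 9, 7, 6 and 3, lay below the median of the other pairs. The mean excess rho was 0.0022 (p = 0.042), and over 5 measures p ran from 0.014 to 0.53, with 3 of them below 0.05.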
